A study of Homo sapiens with 18 samples.

How the data were processed

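Poly(A)-selected mRNA and ribosome footprints of NCI-H1975 cells were sequenced in 18 libraries, 3 for each of 6 groups (Scramble, sgControl and sgDAMP, each as mRNA and as footprints). Per the labels, cells for ribosome profiling were harvested after 100 micrograms per ml cycloheximide, lysates were digested with the nuclease of a commercial ribosome profiling kit, and ribosomal RNA was depleted. The authors name Trimmomatic 0.30, HISAT2 2.1.0, SAMtools 1.10, HTSeq 0.11.2 and edgeR as their tools and GRCh38 as the genome build. The deposited values are raw counts in the form HTSeq writes, whole numbers for 61487 genes per library with 5 closing lines on reads assigned to no gene. The annotation release, the strand setting of the counting and the handling of reads with several positions are not given in the sources used here. Genes whose span overlaps another gene, copies of histones, and HSPA1A with HSPA1B are therefore uncertain. Gene symbols, positions and biotypes came from a GRCh38 annotation that names 19315 of the counted genes as protein-coding and 5284 as lncRNAs, 2153 of the lncRNAs with a span that overlaps a coding span.

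Depth is the sum of gene counts per library. The share of reads assigned to no gene was 54.04% to 54.35% in Scramble mRNA, 22.24% to 24.24% in the other mRNA libraries, 95.65% to 95.82% in Scramble footprints, 65.81% to 66.37% in sgControl footprints and 69.7% to 69.98% in sgDAMP footprints. CPM (counts-per-million) values are relative to all gene counts of a library unless a fit scales them. Agreement of the libraries of a group was tested by a chi-square statistic per gene against Poisson sampling, over genes with a summed count of at least 30. The correlation between libraries with the same replicate number in different groups ran from -0.505 to 0.433 and gave no sign of pairing. It could not show pairing with sgControl or sgDAMP footprints, whose libraries differ by little more than sampling noise. The models of the comparisons hold no pairing term, and a replicate block was run as an alternative. Footprint ratios between sgControl and sgDAMP carry exact Clopper-Pearson 95% intervals on the summed counts with library scaling. These intervals, and floors of 3 counts over a group used where a group has 0 counts, cover counting error only, since reads without molecular identifiers are not independent molecules.

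The 4 comparisons, the main tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Genes were filtered with filterByExpr (minimum count 10) and scaled by TMM (trimmed mean of M values). The scaling was done within each assay, except in Scramble cells, where it ran over the libraries of both assays together. They were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were sgDAMP against sgControl in mRNA, the same in footprints, the interaction of assay and condition over both (footprints relative to mRNA), and footprints against mRNA in Scramble cells. The mRNA comparisons give SD and SE over 3 libraries per group. All p-values are two-sided. The scaling sets the zero point: against TMM, total-count scaling shifted the median tested gene by 0.138 in mRNA, 0.217 in footprints, 0.109 in the interaction and -2.843 in Scramble cells, and upper-quartile scaling by 0.11 in Scramble cells. Changes are relative to the TMM zero point.

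Gene lists, 34 in all, covered translation and RNA modification, mitochondria, the cell cycle, stress responses, signalling, metabolism, epithelial and matrix genes, noncoding RNAs and markers of other cell types. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with the Benjamini-Hochberg adjustment over the lists of a comparison. Members were also counted after adjustment over the list alone. Camera with an estimated correlation and fry were run beside it. Lists of transcripts tied to YTHDF1 and of micropeptide lncRNAs came from general knowledge of the field, and the second holds DSP-AS1, the gene the study chose.

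Named genes were DSP-AS1, DSP and YTHDF1 in each comparison. To these came the 10 highest and 10 lowest log2 changes among called protein-coding genes with a mean log2 CPM of at least 3 and, between sgControl and sgDAMP, no overlap between groups. In each list up to 4 called members with the smallest p were named, and in Scramble cells up to 15 lncRNAs with at least 10 footprints in each library. The span of a lncRNA took the place of its exons in the overlap rule, since the annotation at hand gives spans.

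Alternatives were size factors of DESeq2 1.42.0, upper-quartile and total-count scaling, no filter, at least 10 counts in every library, the DESeq2 Wald test, limma-voom, a log2 change of at least 1, coding genes alone, a replicate block, joint fits with the other libraries, and leaving out each library in turn. Chosen after the data were seen were a fit with the footprint libraries of each group summed to 1 sample, a fit without the 44 genes that vary within sgControl footprints, and a fit with 1 surrogate variable from sva 3.50.0. In the summed fit of footprints the Scramble libraries give the spread, and the lone sample of each condition is assumed to vary like them. In the summed fit of the interaction the mRNA libraries give the spread. Other splits of the libraries into groups of 3 were fitted in the same way, 10 for each comparison with the real one.

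The tests were tried on simulated counts with the mean and spread of each comparison, except that in Scramble cells both assays took the means of the mRNA libraries. Of 100 genes changed by 1 and 100 changed by 2 on the log2 scale, the mRNA test recovered 18 and 75, the footprint test 87 and 99, the interaction 6 and 68, and the Scramble test 29 and 56, with false calls of 7%, 6.5%, 8.6% and 4.5%. A list of 30 genes shifted by 0.5 was called in all 4, with adjusted p from 2.69e-15 to 0.034, and 0 of 30 unshifted lists were called. Genes were simulated independently of each other, so this does not test false list calls where the genes of a list vary together. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.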

Results

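NCI-H1975, an established lung adenocarcinoma cell line, was profiled in 18 libraries that form 6 groups of 3. Each of 3 conditions, named Scramble, sgControl and sgDAMP in the labels, was measured by poly(A) mRNA sequencing and by ribosome profiling, in which the RNA stretches protected by ribosomes (footprints) are sequenced. DAMP is the peptide the labels assign to the lncRNA gene DSP-AS1, and sgDAMP cells carry its knockout. The file names of these libraries say sgTIAMP in place of sgDAMP, and files were joined to labels by accession. The Scramble libraries address which lncRNAs are occupied by ribosomes, and the sgControl and sgDAMP libraries address which mRNAs differ in amount or translation without the peptide. Gene counts per library ranged from 10859527 to 12424884 in Scramble mRNA, from 17098397 to 17464782 in sgControl mRNA and from 17171514 to 17455799 in sgDAMP mRNA. In footprints they ranged from 1035159 to 1302852 in Scramble, from 6845899 to 7840852 in sgControl and from 6207783 to 6864945 in sgDAMP. Protein-coding genes held 79.03% to 79.45% of the sgControl footprints and 76.45% to 76.74% of the sgDAMP footprints. In the Scramble footprints they held 6.38% to 20.21%, or 83167 to 239285 counts per library.

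The labels do not say whether replicates are separate cultures. The 3 footprint libraries of sgDAMP agree within sampling noise for most genes (mean chi-square per degree of freedom 0.910 over the lowest 99% of genes), and 12 genes, among them MT-RNR2 and RPS19, differ beyond it. Those of sgControl also agree for most genes (0.887), but 44 genes, among them ENO1, CDK4, EGFR and MDM2, differ beyond it. Each of these groups therefore counts as 1 sample, its libraries are summed, and its values carry 95% counting intervals in place of a spread between replicates. On the same measure the values were 38.5 for sgControl mRNA, 63.5 for sgDAMP mRNA, 4.10 for Scramble mRNA and 5.33 for Scramble footprints, whose libraries differ well beyond counting noise.

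DSP-AS1 (ENSG00000261189, a lncRNA on chromosome 6 from 7540451 to 7543083 of GRCh38, whose span overlaps that of DSP) lost nearly all footprints in sgDAMP, with no detectable change in its transcript. Its footprints summed to 567 counts in sgControl and to 2 counts in sgDAMP, 292 times lower (95% counting interval 80.4 to 2410). In mRNA it stood at 18 CPM (counts-per-million, SD 1.04, n = 3) in sgControl and at 18.9 CPM (SD 0.462, n = 3) in sgDAMP, a log2 change of -0.07 with TMM (SE 0.27, adjusted p = 0.957) that turns to 0.07 with total counts (adjusted p = 0.965), the scaling of the CPM values. In Scramble cells it reached 23.7 CPM in mRNA (SD 3.14, n = 3) and 246 CPM in footprints (SD 62.9, n = 3). Whether Scramble libraries were counted with the same settings as the others is not given, so levels across them are uncertain. Its footprints relative to its mRNA fell by 7.98 on the log2 scale in sgDAMP (SE 0.45, adjusted p = 7.10e-08), a fit that treats the footprint libraries as replicates, and by 8.02 (SE 0.80, adjusted p = 5.84e-04) with those of each group summed to 1 sample. Because the strand setting of the counting is not given, reads of the overlapping DSP gene are not excluded from its mRNA and Scramble counts, and those levels are uncertain to that extent. In sgDAMP footprints DSP held 3328 counts beside the 2 of DSP-AS1, and DSP held 3136 in sgControl footprints. This argues against DSP reads as the source of the DSP-AS1 footprints in sgControl, if both groups were counted alike.

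DSP (ENSG00000096696, chromosome 6, 7541671 to 7586714), which encodes the desmosomal protein desmoplakin, had similar footprints in both conditions, 3136 counts in sgControl and 3328 in sgDAMP (ratio 1.03, interval 0.982 to 1.08). This depends on the scaling, since DSP passed as higher in sgDAMP with total counts (log2 change 0.26, adjusted p = 4.83e-10) and upper-quartile scaling (0.11, adjusted p = 0.00595). Its mRNA averaged 63.5 CPM (SD 6.43, n = 3) in sgControl, 48.7 CPM (SD 17.7, n = 3) in sgDAMP and 165 CPM (SD 21.1, n = 3) in Scramble cells. The log2 change between sgControl and sgDAMP mRNA was -0.55 (SE 0.29, adjusted p = 0.862). YTHDF1 (ENSG00000149658, chromosome 20, 63195429 to 63216131) encodes a reader of N6-methyladenosine that the series title links to the peptide. Its footprints went from 160 to 234 counts, a ratio of 1.42 (1.16 to 1.75), while its mRNA changed by -0.27 (SE 0.25, adjusted p = 0.864). With the footprint libraries of each group summed to 1 sample, YTHDF1 did not pass (log2 change 0.475, adjusted p = 1). Footprints relative to mRNA changed by 0.59 for DSP (SE 0.31, adjusted p = 0.334) and by 0.77 for YTHDF1 (SE 0.26, adjusted p = 0.120).

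**Figure D1:**
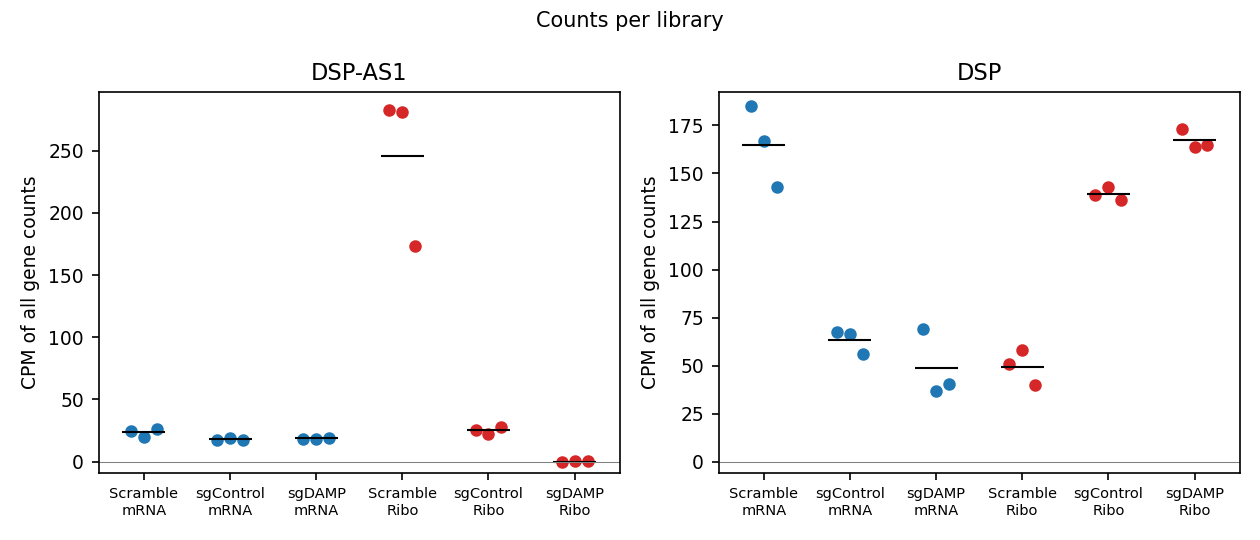
DSP-AS1 and DSP in CPM (relative to all gene counts), with one point per library in each of the 6 groups and a line at each group's mean. DSP-AS1 footprints averaged 25.2 CPM in sgControl and 0.0973 CPM in sgDAMP, while its mRNA averaged 18 and 18.9 CPM.

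To find lncRNAs with ribosome occupancy, lncRNAs with at least 10 footprints in each Scramble footprint library were counted. There were 14, against 1624 protein-coding genes that met the same rule. The snoRNA host genes GAS5, SNHG5 and SNHG1 held the most, with 16400, 5993 and 2703 summed footprints, or 54.6%, 19.9% and 9.0% of all lncRNA footprints. DSP-AS1 ranked 4 with 852 of 30042 lncRNA footprints (2.84%; 3.67%, 2.53% and 2.39% in the 3 libraries). The order differs in the deeper sgControl footprints, where DSP-AS1 has 567, MALAT1 8364, SNHG29 5847, LINC01962 5197, GAS5 147 and SNHG5 17. In Scramble footprints MALAT1 and NEAT1, RNAs retained in the nucleus, had 566 and 44. The remaining 8 of the 14, ZSCAN16-AS1, LINC01962, IGFL2-AS1, PRMT5-DT, SNHG19, SNHG8, SNHG29 and LINC00324, had from 42 to 450 in Scramble footprints.

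Of the 14 lncRNAs, 8 have spans clear of any coding gene (SNHG5, SNHG1, MALAT1, LINC01962, SNHG19, SNHG8, NEAT1 and LINC00324). DSP-AS1 and GAS5 are not among them, so reads of a neighbouring gene are not excluded from their counts. Relative to mRNA, footprints were higher by 13.62 on the log2 scale for SNHG5 (SE 0.66), 5.73 for SNHG1 (SE 0.37), 5.74 for GAS5 (SE 0.40) and 4.59 for MALAT1 (SE 0.28), and lower for NEAT1 (-1.75, SE 0.28), all past the threshold. The SNHG5 value rests on 43 summed mRNA counts against 5993 footprints. Whether the reads of these lncRNAs come from ribosomes was not tested, and MALAT1, retained in the nucleus, is among those higher. A minimum of 5 footprints gave 29 lncRNAs and a minimum of 30 gave 8, and the same rule applied to the deeper sgControl footprints gave 204. Leaving out each Scramble footprint library in turn gave 14 to 20.

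**Figure D2:**
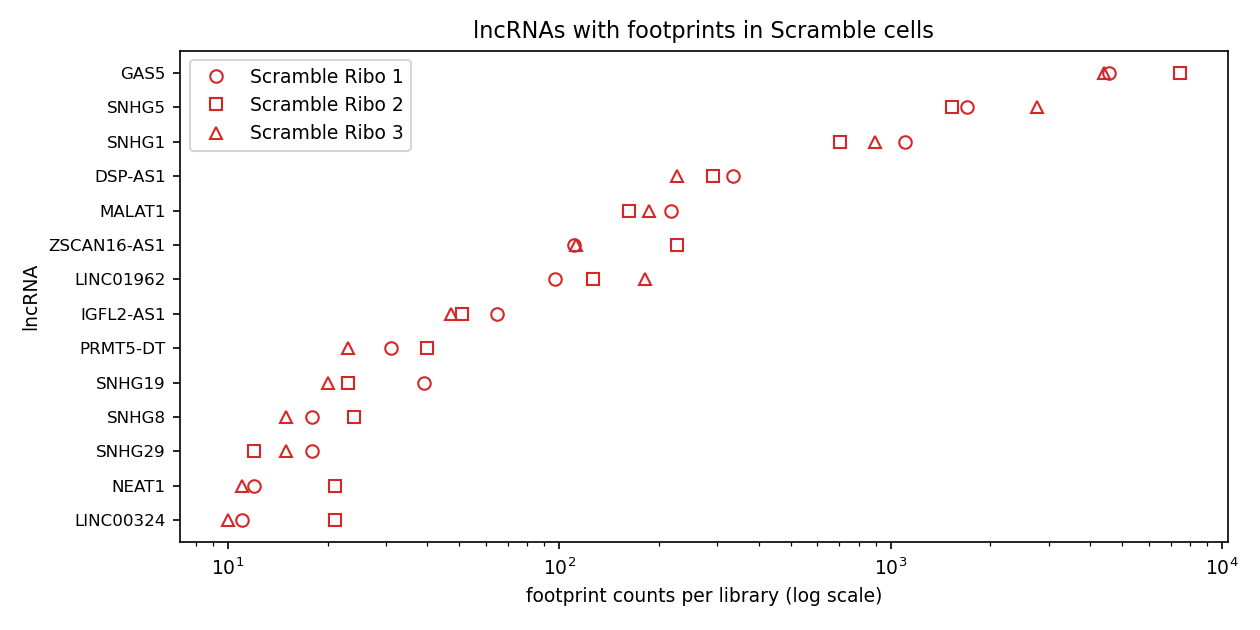
Footprint counts in each of the 3 Scramble footprint libraries for the 14 lncRNAs with at least 10 in every library, on a log axis, with one point per library. GAS5 holds 16400 summed footprints and DSP-AS1 holds 852, the fourth highest sum.

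Comparing footprints with mRNA in Scramble cells asks how ribosome occupancy is spread over transcripts in the cells used for the lncRNA search. DSP-AS1 had 79.6 times more footprint than mRNA signal, a log2 ratio of 6.31 (SE 0.30, n = 3 against 3, adjusted p = 5.57e-16) that becomes 3.37 (SE 0.48, adjusted p = 1.15e-05) with total-count scaling. DSP and YTHDF1 had ratios of 1.17 (SE 0.22) and 1.94 (SE 0.20), which turn to -1.74 and -0.94 when libraries are scaled by total count. All changes in this comparison are relative to a median gene at -0.68 under TMM scaling. Replication-dependent histones, whose mRNAs lack poly(A) tails, were higher in footprints for 42 of 44 members (42 adjusted over the list alone, none lower), with a median of 10.96 (10.66 with the 11 members without mRNA counts at their bound). The list was called with adjusted p = 1.96e-46, and adjusted p = 0.239 with an estimated correlation. H2AC17 had 0 mRNA counts against 1491 footprints, at least 29200-fold higher by its counting interval and 36000-fold against a group floor of 3 counts. H4C5 had 3 against 703, a ratio of 17000 (5780 to 82500). Reads shared between the near-identical histone copies make single histone values uncertain.

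Among the other lists with higher footprints, every median but that of histones falls below 0 when libraries are scaled by total count, so these directions hold only relative to the median gene. Nuclear-encoded oxidative phosphorylation genes were higher for 57 of 72 and lower for 4 (58 and 4 adjusted over the list alone), with a median of 1.44 (adjusted p = 0.297 with an estimated correlation) and COX8A at 5.43 (SE 0.18) and NDUFB6 at 4.49 (SE 0.19). Mitosis genes were higher for 33 of 38 and lower for 1 (34 and 1 adjusted over the list alone). Their median was 2.02 (adjusted p = 0.239 with an estimated correlation). AURKB, a mitotic kinase, stood at 4.01 (SE 0.38) and PTTG1, the securin, at 3.94 (SE 0.27). DNA replication genes were higher for 22 of 42 (24 adjusted over the list alone), with a median of 1.28 (adjusted p = 0.308 with an estimated correlation) and TK1, thymidine kinase, at 3.42 (SE 0.26). Cholesterol and fatty acid synthesis genes were higher for 22 of 32 and lower for 2 (24 and 2 adjusted over the list alone; adjusted p = 0.297 with an estimated correlation), with EBP, a sterol isomerase, at 4.07 (SE 0.30). The proteasome (18 higher and 3 lower of 30, 18 and 3 adjusted over the list alone), ER chaperones (13 and 3 of 23, 14 and 3 adjusted over the list alone) and mitochondrial ribosomal proteins (22 and 6 of 61, 23 and 6 adjusted over the list alone) had medians of 0.79, 0.72 and 0.39. Their adjusted p was 0.387, 0.387 and 0.463 with an estimated correlation.

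Lower footprints than mRNA marked the integrated stress response, in which 26 of 32 members were lower and 2 higher (26 and 2 adjusted over the list alone) with a median of -2.14 (-2.07 with 3 members without footprints at their bound; adjusted p = 0.297 with an estimated correlation). ATF4, its central transcription factor, stood at -4.31 (SE 0.33), TRIB3 at -3.33 (SE 0.29) and CEBPG at -4.03 (SE 0.37). Elongation factors and other mRNAs with a terminal oligopyrimidine (TOP) motif were lower for 8 of 12 and higher for 2 (9 and 2 adjusted over the list alone; adjusted p = 0.297 with an estimated correlation), with EEF1A1 at -3.77 (SE 0.31). Cytosolic ribosomal proteins were lower for 39 of 77 and higher for 19 (41 and 20 adjusted over the list alone; adjusted p = 0.431 with an estimated correlation), with RPS2 at -5.82 (SE 0.37). Initiation factors (19 lower and 7 higher of 41, 20 and 8 adjusted over the list alone), immediate-early genes (13 and 2 of 21, 13 and 2 adjusted over the list alone) and the PI3K pathway (12 and 1 of 21, 12 and 1 adjusted over the list alone) had medians of -0.75, -1.11 and -1.06. Their adjusted p was 0.333, 0.431 and 0.387 with an estimated correlation. The median tested gene lay at -0.68, close to the medians of initiation factors and of cytosolic ribosomal proteins (-0.82). With total-count scaling 1 of the 6 lists called lower kept its call, against 5 of the 8 called higher. The immediate-early gene IER2 had no footprint against 5555 mRNA counts. It was at least 20.8-fold lower by its counting interval and 25.6-fold lower against a group floor of 3 counts. Outside the called lists, CCL2, a chemokine, stood at 7.43 (SE 0.23) and FTH1, the ferritin heavy chain, at -4.98 (SE 0.41).

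In all, edgeR called 6418 of 14432 genes in Scramble cells (2464 higher in footprints and 3954 lower), with protein-coding genes split into 2044 and 2969 and lncRNAs into 37 and 324 of 893. Camera called 14 of 32 lists, with adjusted p from 1.96e-46 for histones to 0.0428 for the PI3K pathway, and none with an estimated correlation. The smallest adjusted p with an estimated correlation was 0.239, for histones and mitosis genes. Total-count scaling called 13530 genes and 6 lists, and a filter of at least 10 counts in every library called 1143 genes and 6 lists.

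Comparing sgDAMP with sgControl mRNA asks which transcripts differ in amount without the peptide. Inflammatory genes controlled by NF-kB had lower mRNA as a group in sgDAMP, with a median log2 change of -0.56 over 24 members (adjusted p = 7.43e-08, and adjusted p = 0.404 with an estimated correlation). Genes of TGF-beta signalling and the extracellular matrix had a median of -0.42 over 33 (adjusted p = 4.08e-07, and adjusted p = 0.703 with an estimated correlation). The inflammatory cytokines CSF2 (-2.14, SE 0.58) and CXCL8 (-2.08, SE 0.60) were the 2 NF-kB members lower when adjusted over the list alone (adjusted p = 0.0475 for both). Both genes lie outside the rule for named genes and were chosen after their values were seen. Mitosis genes had a median of 0.33 over 39 members, higher in sgDAMP (adjusted p = 0.00277, and adjusted p = 0.703 with an estimated correlation).

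Smaller negative medians were found for immediate-early genes (-0.29 over 22, adjusted p = 0.00299, and adjusted p = 0.884 with an estimated correlation) and the integrated stress response (-0.21 over 32, adjusted p = 0.0149, and adjusted p = 0.404 with an estimated correlation). The same holds for hypoxia and glycolysis (-0.18 over 33, adjusted p = 0.0325, and adjusted p = 0.703 with an estimated correlation) and cholesterol and fatty acid synthesis (-0.15 over 32, adjusted p = 0.0350, and adjusted p = 0.688 with an estimated correlation). Over all genes tested, 0 members of these 7 lists passed, and adjusted over the list alone 1 matrix member was lower and 0 passed in the mitosis, immediate-early, stress response, hypoxia and cholesterol lists. With fry 0 lists were called. The p53 targets had a median of -0.11 and a mean of 0.02 over 25 members (adjusted p = 0.783). Of the markers of other cell types, 2 fibroblast and 2 leukocyte genes were abundant enough to test and 0 passed.

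No single gene passed in mRNA with edgeR, which called 0 of 14032 (n = 3 against 3, 741 at an unadjusted p under 0.05, smallest adjusted p = 0.220), while limma-voom called 0 and DESeq2 21, of which 1 was higher and 20 lower. Values of the groups did not overlap for 1607 genes (11.5%, where chance gives 10%). The first principal component, 55.7% of the variance, did not follow the condition, running from 0.669 to -0.30 in sgControl and from 0.106 to -0.636 in sgDAMP. Leaving out replicate 3 of sgControl mRNA gave 6 genes, leaving out replicate 1 of sgDAMP mRNA gave 14 lists in place of 7, no count filter gave 14 genes, a fit with all 9 mRNA libraries gave 1, and 1 surrogate variable added after the data were seen gave 41. On simulated counts of this spread the test recovered 75 of 100 genes changed by 2 on the log2 scale and 18 of 100 changed by 1.

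Comparing sgDAMP with sgControl footprints asks how ribosome occupancy differed without the peptide. Targets of the tumour suppressor p53 rose in sgDAMP, 21 of 24 with 2 falling and 1 not passing (21 and 2 adjusted over the list alone), with a median log2 change of 1.19. These counts compare the reads of 1 sample per condition, and with the libraries of each group summed only BTG2 passed as higher and MDM2 and PLK3 as lower. BTG2, an antiproliferative gene, went from 118 to 1239 footprints, 10.2-fold higher (8.44 to 12.4), and FDXR, ferredoxin reductase, from 92 to 717, 7.57-fold higher (6.09 to 9.52). CDKN1A, the cell cycle inhibitor p21, rose 2.29-fold (2.18 to 2.41) and BAX, a promoter of apoptosis, 1.68-fold (1.62 to 1.75). The 2 that fell were MDM2, the ubiquitin ligase that restrains p53 (14 times lower, 13.7 to 14.3), and PLK3 (35.5 times lower, 31.1 to 40.6).

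Footprints of cell division genes fell together. Of 39 mitosis genes 36 fell and 0 rose (36 adjusted over the list alone), with a median of -0.49, the mitotic kinase PLK1 1.79 times lower (1.73 to 1.85), CDK1 1.58 times (1.54 to 1.63) and the cyclin CCNB1 1.49 times (1.46 to 1.52). Of 40 DNA replication genes 32 fell and 3 rose (32 and 3 adjusted over the list alone), with a median of -0.61, the replicative helicase subunits MCM4 2.09 times lower (2.03 to 2.15) and MCM5 1.89 times (1.82 to 1.97), and RRM1, a subunit of ribonucleotide reductase, 14.5 times (14.2 to 14.9). Of 49 replication-dependent histones 42 fell and 2 rose (42 and 2 adjusted over the list alone), with a median of -0.42 and H3C3 1.76 times lower (1.73 to 1.80), though reads shared between histone copies leave single histones uncertain. Of 10 transcripts that others tied to translation through YTHDF1, 8 fell and 0 rose (8 adjusted over the list alone), with a median of -0.38, including CDK4, a kinase of the G1 phase (115 times lower, 104 to 126), CCND1, its cyclin partner (1.80 times, 1.75 to 1.85), and USP14, a deubiquitinase (1.25 times, 1.21 to 1.29).

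These lists kept their calls with an estimated correlation, but that correlation comes from libraries of 1 sample per condition and says nothing on samples that vary together. Camera gave adjusted p = 2.19e-12 for p53 targets, 1.17e-17 for mitosis, 9.31e-16 for DNA replication, 6.02e-24 for histones and 4.92e-06 for YTHDF1-tied transcripts. The adjusted p with an estimated correlation was 0.0268 for p53 targets, 0.00718 for mitosis and histones, 0.0181 for DNA replication and 0.0415 for YTHDF1-tied transcripts. With the libraries of each group summed to 1 sample, the YTHDF1-tied transcripts lost their call and the other lists kept theirs. The fit with summed libraries takes its spread from the Scramble footprints. With 1 sample per condition it cannot tell an effect of the knockout from another difference between the samples, so a kept call is no test of stability. In that fit single members passed in 2 of the 4 cell division and YTHDF1-tied lists, RRM1 and CDK4, both lower, and 0 in mitosis and histones.

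The remaining 7 list calls in footprints were lost with an estimated correlation, and with libraries summed only ATF4, BTG2 and ENO1 passed among their members. Cholesterol and fatty acid synthesis genes fell for 23 of 32 and rose for 2 (23 and 2 adjusted over the list alone), with SCD, a desaturase of fatty acids, 1.44 times lower (1.42 to 1.47) and a median of -0.38 (adjusted p = 1.38e-07, and adjusted p = 0.0835 with an estimated correlation). Integrated stress response genes fell for 16 of 28 and rose for 7 (16 and 7 adjusted over the list alone), with ATF4 6.45 times lower (6.12 to 6.80) and a median of -0.29 (adjusted p = 0.00176, and adjusted p = 0.0836 with an estimated correlation). Immediate-early genes rose for 11 of 19 and fell for 4 (11 and 4 adjusted over the list alone), with KLF6 2.36-fold higher (1.87 to 3) and a median of 0.49 (adjusted p = 0.0179, and adjusted p = 0.126 with an estimated correlation). Mitochondrially encoded mRNAs rose for 10 of 13 (12 adjusted over the list alone), with MT-ATP8 1.92-fold higher (1.72 to 2.15) and a median of 0.16 (adjusted p = 1.68e-04, and adjusted p = 0.297 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes rose for 32 of 71 and fell for 13 (33 and 14 adjusted over the list alone), with NDUFB2 1.19-fold higher (1.15 to 1.24) and a median of 0.09 (adjusted p = 0.0277, and adjusted p = 0.148 with an estimated correlation). Heat shock genes fell for 8 of 14 and rose for 2 (8 and 2 adjusted over the list alone), with a median of -0.17 that turns to 0.05 with total-count scaling (adjusted p = 0.00176, and adjusted p = 0.0987 with an estimated correlation). Hypoxia and glycolysis genes fell for 15 of 30 and rose for 6 (15 and 6 adjusted over the list alone), with a median of -0.12 that turns to 0.10 with total-count scaling (adjusted p = 0.0170, and adjusted p = 0.116 with an estimated correlation).

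The translation machinery moved both ways, on the reads of 1 sample per condition, and 0 members of the 3 lists below passed with the libraries of each group summed. Initiation factors rose for 15 of 41 and fell for 16, cytosolic ribosomal proteins rose for 27 of 75 and fell for 36, and writers, erasers and readers of N6-methyladenosine rose for 4 of 21 and fell for 3, with the same counts adjusted over the list alone and adjusted p of 0.920, 0.403 and 0.870. Initiation factors had a mean of 0.06 but a test direction below the other genes, ribosomal proteins a median of -0.04 and a mean of 0.001, and with total-count scaling both medians lie above 0 (0.22 and 0.18). EIF3L, a subunit of initiation factor eIF3, was 1.51 times lower (1.45 to 1.58) and the ribosomal protein RPS25 1.81-fold higher (1.72 to 1.91). The single fibroblast marker tested, COL1A1, was higher (30 and 120 footprints), and the single leukocyte marker tested did not pass.

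**Figure D3:**
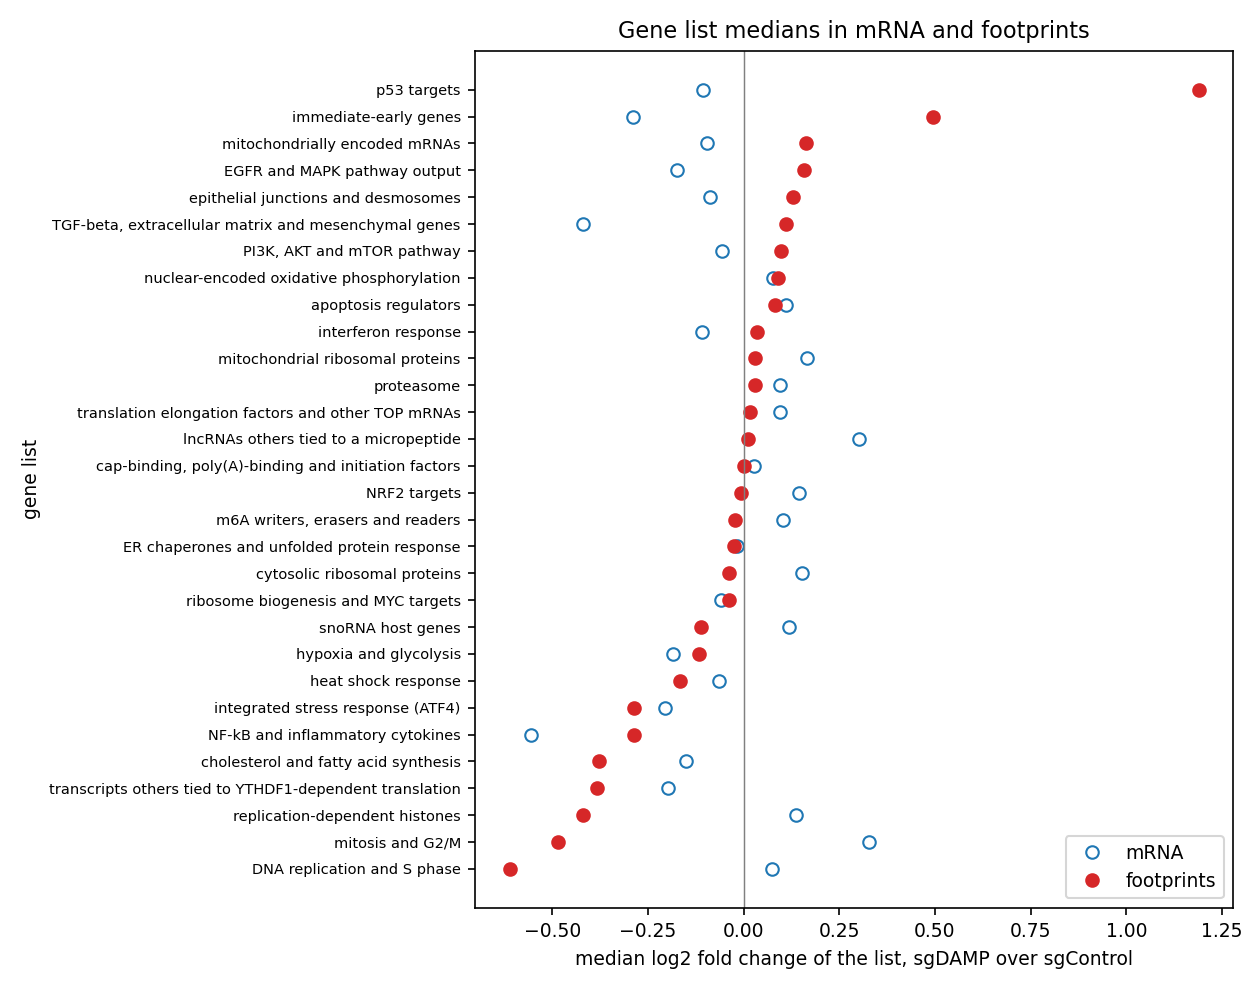
Median log2 change between sgControl and sgDAMP of 30 gene lists in mRNA (open blue points) and footprints (red points). The p53 targets lie at -0.11 in mRNA and 1.19 in footprints and mitosis genes at 0.33 and -0.49, while heat shock and hypoxia genes lie at -0.17 and -0.12 in footprints, signs that turn with total-count scaling.

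Among coding genes with a mean log2 CPM of at least 3, the deepest single losses of footprints reached far beyond the changes of the lists. BCL2L1, an inhibitor of apoptosis, went from 24997 to 63 footprints, 408 times lower (319 to 531). TWIST1, a transcription factor of mesenchymal cells, was 218 times lower (168 to 290), the growth factor BMP7 164 times (79.1 to 408), RGCC 113 times (54.4 to 281) and the growth factor MDK 53.9 times (38.2 to 78.5), followed by OLFM1, PTPN14 and MAPK8IP1 at 43.5, 39.8 and 38.5 times. The glycolytic enzyme ENO1 was 21.1 times lower (20.8 to 21.4) and EGFR, a receptor kinase, 18.6 times (18.2 to 19.0). Counts of ENO1, EGFR, CDK4, BCL2L1, TWIST1, MDM2, RRM1, ATF4, PLK3, MDK, PTPN14 and MAPK8IP1 differed beyond sampling noise among the 3 sgControl footprint libraries. Among the same coding genes the highest gains after BTG2 were DNAI3 (9.34-fold, 6.51 to 13.8), ZNF845 (8.16-fold, 5.82 to 11.7) and FDXR, with TPM4, a tropomyosin, at 5.04-fold (4.68 to 5.44).

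In total edgeR called 6957 of 12509 genes in footprints (3459 higher, 3498 lower), 742 of them at least 2-fold higher and 474 at least 2-fold lower, and DESeq2 called 4894. Protein-coding genes split into 2925 and 2700 of 9989, and lncRNAs into 84 and 44 of 259. These calls compare the reads of 1 sample per condition. With the libraries of each group summed and the spread taken from the Scramble footprints, 58 genes passed (7 higher, 51 lower) and 5 lists.

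**Figure D4:**
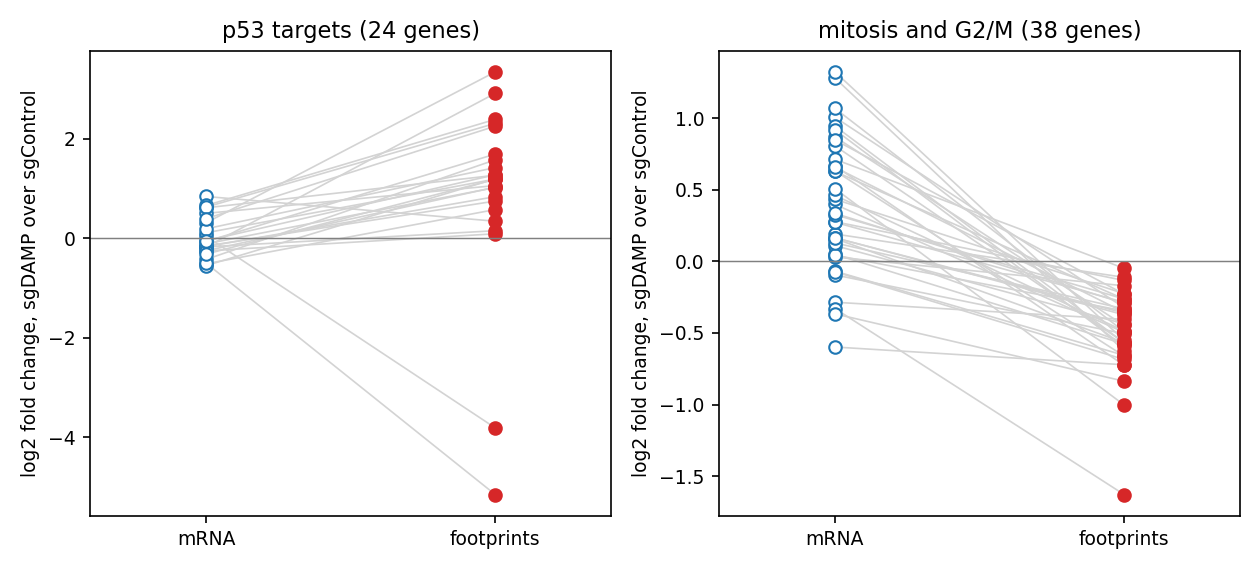
Log2 change between sgControl and sgDAMP of each of 24 p53 targets and 38 mitosis genes in mRNA and in footprints, with lines joining the values of a gene. In footprints 21 p53 targets rose and 36 of the 39 mitosis genes tested there fell.

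Footprints relative to mRNA, fitted as the interaction of assay and condition, ask whether translation changed beyond transcript amount. SE and p treat the 3 footprint libraries of a group as replicates. With those libraries summed to 1 sample, a fit whose spread comes from the mRNA libraries alone, the footprints have no spread of their own, so the 8 lists still called are no test of stability. In that fit, of their members only RRM1, MDM2, PLK3, CDK4 and DSP-AS1 passed as lower and BTG2 and FDXR as higher, and 0 passed in mitosis, histones and heat shock. DNA replication genes had lower footprints relative to mRNA in sgDAMP, with 6 of 40 lower (16 adjusted over the list alone) and a median of -0.56 (adjusted p = 6.78e-08, and adjusted p = 0.00379 with an estimated correlation). RRM1 fell by 4.21 (SE 0.31), GINS1, part of the replicative helicase, by 1.37 (SE 0.26), RRM2 by 1.12 (SE 0.23) and FEN1, a flap endonuclease, by 1.09 (SE 0.24). The p53 targets had 9 higher and 2 lower of 24 (17 and 2 adjusted over the list alone) and a median of 1.19 (adjusted p = 6.78e-08, and adjusted p = 0.0635 with an estimated correlation), with FDXR at 3.10 (SE 0.30), BTG2 at 3.04 (SE 0.30) and MDM2 at -3.85 (SE 0.32). Mitosis genes had 3 lower of 38 (12 adjusted over the list alone) and a median of -0.68 (adjusted p = 9.72e-10, and adjusted p = 0.0635 with an estimated correlation), with DLGAP5 at -1.89 (SE 0.40) and the spindle motor KIF11 at -1.37 (SE 0.29).

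Immediate-early genes had 2 higher of 18, BTG2 and the transcription factor KLF4 (6 adjusted over the list alone), and a median of 0.68 (adjusted p = 2.93e-06, and adjusted p = 0.287 with an estimated correlation). Histones had 3 lower of 29 (3 adjusted over the list alone) and a median of -0.39 (adjusted p = 0.00841, and adjusted p = 0.629 with an estimated correlation). Heat shock genes had 1 lower of 14, HSPA1B (2 adjusted over the list alone), with a median of -0.44 (adjusted p = 0.0214, and adjusted p = 0.140 with an estimated correlation), and HSPA1B shares reads with its near-identical copy HSPA1A. YTHDF1-tied transcripts had 1 lower of 10, CDK4 (1 adjusted over the list alone), with a median of -0.15 (adjusted p = 1.29e-04, and adjusted p = 0.0991 with an estimated correlation), and did not pass without the 44 genes that vary within sgControl footprints (median -0.05, adjusted p = 0.468). Micropeptide lncRNAs had 1 lower of 6, DSP-AS1 itself, which is the study's own target and no independent evidence (1 adjusted over the list alone, median -0.43, adjusted p = 3.44e-04, and adjusted p = 0.0635 with an estimated correlation).

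Among single genes the deepest falls relative to mRNA after DSP-AS1 and BCL2L1 (-8.62, SE 0.34, adjusted p = 2.32e-09) were TWIST1 (-7.36, SE 0.40), CDK4 (-6.80, SE 0.30) and MDK (-5.62, SE 0.41), with EZH2, a histone methyltransferase, at -5.23 (SE 0.40). The highest value of a coding gene was that of S100A9, a calcium-binding protein, at 6.95 (SE 1.08), which rests on 1 footprint in sgControl against 154 in sgDAMP (ratio 150, 26.5 to 5950). RND1 rested on 1 against 44 (ratio 42.8, 7.28 to 1730) and ZNF629 on 3 against 91 (ratio 29.5, 9.77 to 146).

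The interaction called 359 of 10168 genes (205 higher, 154 lower), of which 344 were also called in the same direction in footprints. The split depends on the scaling, with 159 higher and 194 lower of 353 with TMM over all 12 libraries. Across these 10168 genes, which are not independent replicates, changes in mRNA and in footprints had a Pearson r of 0.072 and a Spearman rho of 0.071. The count moved with the setting: 698 genes without a count filter, 174 (73 higher, 101 lower) with at least 10 counts in every library, 618 with DESeq2, 224 with limma-voom, 220 with a replicate block, 52 (7 higher, 45 lower) with footprint libraries summed and 237 without the 44 genes. It was 1165 (492 higher, 673 lower) without sgControl mRNA replicate 3, 659 without sgDAMP mRNA replicate 1 (13 lists in place of 8), 213 without sgControl mRNA replicate 2, and 133, 137 and 122 without sgControl footprint replicate 1, 2 or 3 and 134, 142 and 142 without sgDAMP footprint replicate 1, 2 or 3.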

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

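The tests of the deep footprint losses, of the mRNA changes behind the p53 and mitosis footprints, of variable genes among the mitosis genes and of the growth state were chosen only after the result was seen, the settings without the variable genes and with summed libraries after the data were seen, and the fits of other splits before.

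For footprints relative to mRNA, camera at the preset correlation called p53 targets (median 1.19 over 24 genes), mitosis genes (-0.68 over 38) and DNA replication genes (-0.56 over 40). With an estimated correlation DNA replication genes kept the call (adjusted p = 0.00379), and p53 targets and mitosis genes lost it (adjusted p = 0.0635 for both). These fits of the interaction treat the footprint libraries of 1 sample per condition as replicates. Outside the comparisons, up to 46.9% of uniquely placed reads in Scramble mRNA libraries lay outside annotated features, against 1.19% to 1.56% in the other mRNA libraries, and ambiguous reads were 3.4% to 3.5% against 14.81% to 16.02%. Whether the counting settings were the same is not given. Mitochondrial ribosomal RNA took up to 71.7% of the gene counts in Scramble footprints, against at most 2.42% in sgControl and sgDAMP footprints.

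Apart from DSP-AS1, 53 genes had footprints at least 8-fold lower in sgDAMP, among them BCL2L1, CDK4, ENO1 and EGFR, and together they held 9.87% of all gene counts in sgControl footprints, 0.711% in sgDAMP and 0.126% in Scramble. A loss caused by the knockout would leave Scramble cells, which keep the locus, near sgControl, but the median log2 ratio of Scramble to sgControl over these genes was -4.42 relative to the other genes (quartiles -5.35 and -1.74, other genes -1.56 to 2.41), 37 of the 53 lay nearer to sgDAMP, and 9 had no Scramble footprint. In mRNA the same ratio over 46 of the genes was -0.02 (quartiles -0.99 and 0.76, other genes -1.26 to 1.48), though the counting settings of the Scramble libraries are not known to be the same. The scaling moves all genes alike and is argued against, since with total counts, which centre on no gene, the other genes had a median of 0.23 (quartiles -0.06 and 0.55) while 51 of the 53 stayed at least 8-fold lower. What stays open is reads of another origin in the sgControl footprint libraries. There 64.2% of the genes (34 of 53) differed among the 3 libraries beyond sampling noise. Of the other genes with summed counts at or above the median of the 53, 2.08% (8 of 385) did. Those genes were not matched in depth to the set, which reaches 447454 summed counts, and the test gains power with depth. Within sgDAMP 0 of the 53 differed. The genes were chosen for lower counts there, and for those with few counts this decides nothing, since the test has little power. Others kept many summed counts in sgDAMP (ENO1 21793, NONO 18711 and CTNNB1 18458) and showed no such difference.

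The second pattern is the rise of p53 target footprints and the fall of mitosis footprints in sgDAMP. In the mRNA libraries a change of the mRNAs is argued against, since the p53 target mRNAs had a median of -0.11 (quartiles -0.25 and 0.31) and the mitosis mRNAs a median of 0.33 (quartiles 0.05 and 0.69). Whether those libraries pair with the footprint libraries could not be seen, since the latter differ by little more than sampling noise. A change of the mRNAs in the cells taken for footprints therefore stays open. Variable genes among the mitosis genes, those that differ within sgControl footprints, are argued against for that fall, since 0 of the 39 mitosis genes are variable. For the rise of the p53 targets such variable genes are argued against too, since the only 2 of 24 that vary, MDM2 and PLK3, had fallen. The camera adjusted p of 8.05e-25 of the list without them (2.19e-12 with them, 0.0268 with an estimated correlation) adds nothing. Leaving out members that fell cannot end the call of a rise. A growth state of the cells taken for footprints, apart from the knockout, cannot be told apart from an effect of the knockout, and both stay open. The footprint libraries of each condition agree within sampling noise for most genes and count as 1 sample.

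For each comparison the 6 libraries, or pairs of libraries, of 2 groups can be split in 10 ways, too few for a share under 0.05. In footprints the real split called 6957 genes and the highest other split 0, so 1 of the 10 splits gave as many. For footprints relative to mRNA the values were 359 and 0, with 1 of 10, and in Scramble cells 6418 and 0, with 1 of 10. Where sgControl and sgDAMP footprints enter, this outcome decides nothing. The footprint libraries of a condition count as 1 sample, so any other split mixes both samples on each side. In mRNA the real split called 0 genes, so all 10 splits gave as many, and the highest other split, sgControl 1 and 2 with sgDAMP 1 against the rest, called 958, which points to a structure of the mRNA samples other than the condition.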

How the results depend on the processing

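The tests with summed footprint libraries, without the 44 variable genes and with 1 surrogate variable were chosen only after the result was seen. The mRNA and interaction tests recovered 18 and 6 of 100 simulated genes changed by 1 on the log2 scale and the footprint test 87, which rests on the spread between libraries of 1 sample (coefficient of variation 0.0189, mRNA 0.317) and is not comparable. The lncRNA count moves with the minimum. Of the named genes in footprints, 1440 values under other settings kept direction and side of the threshold, 130 no longer passed, 2 newly passed and 4 changed direction. With a library left out 799 were kept and 5 no longer passed. For named genes of the interaction 614 were kept and 82 no longer passed under other settings, and 505 and 166 with a library left out. In Scramble cells 1133 were kept, 24 no longer passed and 34 changed direction under other settings. Leaving out lncRNAs with an exon on a coding exon was not run, since the annotation gives spans. The cause was not tested for any change of value given here, except where fewer genes or samples enter by construction.

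Genes called in mRNA (0) became 14 with no count filter, 21 with DESeq2, 1 with all 9 mRNA libraries and 41 with 1 surrogate variable, and 0 to 6 with a library left out. Genes called in footprints (6957) became 1216 with a log2 change of at least 1 and 58 with libraries summed, and 6450 to 6669 with a library left out. The interaction (359) became 698 with no count filter, 174 with at least 10 counts in every library, 618 with DESeq2, 224 with limma-voom, 220 with a replicate block, 52 with libraries summed and 237 without the 44 genes, and 122 to 1165 with a library left out. Scramble cells (6418) became 13530 with total counts and 1143 with at least 10 counts in every library, and 4736 to 6525 with a library left out. A replicate block gave 0 in mRNA, 6965 in footprints and 4704 in Scramble cells. With total counts the higher share of called genes went from 49.7% to 77.4% in footprints, from 57.1% to 74.3% in the interaction (45% with TMM over all 12 libraries) and from 38.4% to 3.6% in Scramble cells.

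Lists called in mRNA (7) became 0 with an estimated correlation and 0 with fry, and 6 to 14 with a library left out. Those in footprints (12) became 5 with an estimated correlation, 23 with fry and 5 with libraries summed, and 11 to 12 with a library left out. Those of the interaction (8) became 1 with an estimated correlation and 13 with no count filter, and 7 to 13 with a library left out. Those in Scramble cells (14) became 0 with an estimated correlation, 22 with fry, 6 with total counts and 6 with at least 10 counts in every library, and 12 to 17 with a library left out. The lncRNA count (14) became 29 at a minimum of 5, 8 at a minimum of 30, 8 without spans that overlap coding genes and 204 in sgControl footprints, and 14 to 20 with a library left out.

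Directions turned in mRNA without sgDAMP replicate 2 for ribosomal proteins (-0.13, highest 0.43 without sgDAMP replicate 1), oxidative phosphorylation (-0.14, highest 0.31) and snoRNA hosts (-0.28, highest 0.30), and with 1 surrogate variable for ribosomal proteins (-0.16) and oxidative phosphorylation (-0.14). In footprints fry put matrix (median 0.11), epithelial (0.13) and apoptosis genes (0.083) lower. Total counts turned CANX (0.045), PSMB3 (0.039), PSMD3 (0.033), PSMD1 (0.056), initiation factors (0.22) and ribosomal proteins (0.18). They also changed the sign of the median, but not the test direction, for heat shock and hypoxia genes in footprints. The same holds in Scramble cells for 7 of the 8 lists called higher. In Scramble cells total counts turned DSP (-1.74), YTHDF1 (-0.94), EIF4E (-0.98), MRPL33 (-0.21), MRPL21 (-0.29), MRPL20 (-1.02), MT-ND6 (-0.88), PCNA (-0.45), MCM6 (-0.018), PDIA4 (-0.62), PDIA6 (-0.53), CALR (-0.45), B2M (-0.55), IFI6 (-1.09), HLA-B (-1.22), ISG20 (-1.63), NFKBIA (-0.88), PLAUR (-0.31), ITGA5 (-1.39), THBS1 (-0.29), CDH1 (-1.63), JUP (-1.75), P4HA1 (-1.12), FDFT1 (-0.17), DHCR7 (-0.15), NQO1 (-0.97), TXN (-1.24), PSMB2 (-0.20), PSMB1 (-0.01), PSMB3 (-0.38), MUC1 (-0.24), PMAIP1 (-1.66) and BAX (-1.86), and at least 10 counts in every library turned BAX (-0.061).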

Other observations

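The tests of the chromosome 9 genes were chosen only after the result was seen.

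Gene groups without a list call still held single genes whose footprints relative to mRNA differed in sgDAMP, on 1 footprint sample per condition, and of those in this paragraph only PLAUR and CTNNB1 also passed with the footprint libraries summed. Matrix and mesenchymal genes had 4 higher and 2 lower of 28 (4 and 2 adjusted over the list alone, list adjusted p = 0.335), with ACTA2, smooth muscle actin, at 3.99 (SE 0.62, on 5 and 66 footprints), TAGLN, its partner in contractile cells, at 1.28 (SE 0.32), and PLAUR, the urokinase receptor, at -4.10 (SE 0.29). Epithelial junction genes had 2 higher and 1 lower of 21 (4 and 1 adjusted over the list alone, list adjusted p = 0.368), with the desmosomal plakophilin PKP2 at 2.78 (SE 0.60, on 7 and 52 footprints), the claudin CLDN3 at 2.30 (SE 0.54) and CTNNB1, beta-catenin, at -3.86 (SE 0.30). Interferon response genes had 2 higher of 24 (4 adjusted over the list alone, list adjusted p = 0.296), TAP1, a peptide transporter of antigen presentation, at 1.82 (SE 0.30) and the transcription factor IRF1 at 1.94 (SE 0.45). NRF2 targets had 3 lower of 26 (4 adjusted over the list alone, list adjusted p = 0.0826), HMOX1, heme oxygenase, at -1.69 (SE 0.33), TXNRD1 at -1.28 (SE 0.30) and GCLM at -1.21 (SE 0.31). PLAUR and CTNNB1 had footprints 24.8 (20.9 to 29.5) and 13.6 (13.4 to 13.8) times lower in sgDAMP and belong to the deep losses described above, though PLAUR differs from most of these, with Scramble footprints 2.14 above sgControl on the log2 scale relative to other genes and no difference beyond sampling noise within sgControl.

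Mitochondrially encoded transcripts had uneven footprints in Scramble cells, where MT-ND5 (3.34, SE 0.32) and MT-ND4L (3.28, SE 0.23) had higher footprints than mRNA and MT-ND2 (-3.24, SE 0.38) lower, with 6 of 13 members higher and 2 lower (6 and 2 adjusted over the list alone, list adjusted p = 0.170). Among lncRNAs others tied to a micropeptide, MTLN, which encodes the mitochondrial peptide mitoregulin, stood at 3.11 (SE 0.22) and TUG1 at -3.31 (SE 0.53), with 2 of 9 higher and 2 lower, DSP-AS1 included (2 and 2 adjusted over the list alone, list adjusted p = 0.513). NBDY, SMIM30 and CRNDE of the same list did not pass, at -0.92, 0.07 and 0.02.

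MTAP, CDKN2A and CDKN2B, neighbours on chromosome 9, were near 0 in every library, with 14 summed counts over the 18 libraries, and no difference between groups was tested, since all groups show it. Loss of the stretch that holds them may account for this: MTAP, an enzyme of methionine salvage, did not exceed 0.175 CPM in any of the 9 mRNA libraries, while the flanking coding genes KLHL9 and DMRTA1 had 2529 and 238 summed mRNA counts. By their mean over the same 9 libraries AKR1B10, AKR1C1, AKR1C2, AKR1C3, ALDH1A1, ALDH3A1 and NQO1, reductases and aldehyde dehydrogenases (several of them NRF2 targets), all lay among the top 5% of 12161 coding genes, at 1560 to 5490 CPM against a median of 20.8. Their levels varied between groups. ALDH3A1 averaged 476 CPM in Scramble mRNA and 5720 CPM in sgControl mRNA, and ALDH1A1, the other way, 2450 and 1920 CPM. Cells of a line other than the labelled one could also show the near absence of the chromosome 9 genes and these high means. The 14 counts cannot be told apart from a loss in the labelled line itself, because no reference library of that line is among the data.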
